A study of Arabidopsis thaliana with 36 samples.

How the data were processed

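Cells of 6 root populations of Arabidopsis thaliana (ecotype Columbia) were sorted from GFP lines after 1 h on 140 mM NaCl or on standard medium, and their total RNA was amplified by a two-cycle protocol, per the labels' protocols, with 3 arrays in each of 12 groups. The deposited values are 1 linear intensity per probe set and array, computed with MAS5 per the submitters' processing notes; the version of MAS5 and the scaling are not given in the sources used here. In the deposited values the mean after trimming 2% from each end lay between 250.02 and 250.03 on each of the 36 arrays, so the authors had scaled each array to one trimmed mean. This scaling assumes a constant average level, so a change of most transcripts in one direction is removed by it, and medians of 62.1 to 95.6 show that the distributions were not made equal. MAS5 intensities are noisy near background, and without detection calls, not used here, a low signal could not be told from background. The amplification starts from the 3' end, so transcripts copied less completely lose their 5' signal.

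Of 22810 probe sets, 64 Affymetrix controls were left out of the tests. The table of probe genes gave exactly 1 gene for 13513 probe sets, several for 503 and none for 8730; genes are named only from probe sets with 1 gene, with symbols from that table and the RefSeq annotation of assembly TAIR10.1, of which no coordinate is used. Probe sets entered the tests when above the 40th percentile of their array on at least 3 arrays, which kept 17633, of which 9892 had 1 gene. Sequences were not analysed here, so a probe set shared by related genes, as in the large families named, cannot be assigned to 1 member with certainty.

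Values were transformed as log2(signal + 16), and fold changes are on that scale, which understates the change of low signals. A linear model with a mean for each of the 12 groups was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), which pools the spread over 24 residual degrees of freedom, and probe sets were called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were salt minus standard in each population, their mean, the F-test of the 5 differences between the 6 responses, each response against the mean of the other 5, and the F-tests between populations on each medium. All p-values are two-sided. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

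Genes were named by a rule set before the data were examined: per population the 8 largest rises and 5 largest falls among called probe sets with 1 gene whose salt and standard arrays do not overlap; for the mean response the 10 largest rises and falls with one sign in all 6 populations. Further names were, for the interaction, the 10 largest F values; for each response against the others the 3 largest differences each way; per population the 5 most enriched genes on standard medium; from each list up to 4 members with the smallest adjusted p; and the reporter genes. Before the data were examined, 13 pathway lists with 255 genes and 8 marker lists with 71 genes were also fixed. Only 35 of these 326 genes had a probe set naming 1 gene, and 4 lists had the 3 tested members needed for a list test: ABA and dehydration response, auxin response and transport, cytosolic ribosomal proteins and early stress transcription factors. Lists without a tested member (ABA phosphatases, ion transport, jasmonate, aquaporins, suberin, epidermis, root cap and shoot photosynthesis) gave no result, and the reporters other than AT1G09750 could not be checked. Because of this, 26 gene families were defined from symbol patterns after the table of names was seen and before any change was computed, 25 of which had 3 or more members tested. The plastid pattern was widened to a second style of locus name after values had been seen, so that it took all 69 plastid-encoded genes. The resulting 29 lists were tested with limma's camera at a preset correlation of 0.01 in 7 contrasts, with adjustment over 203 tests, and again with an estimated correlation and with fry.

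The code was tested on simulated data with the real means and spread, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. The other 17433 probe sets were left unchanged and their noise was drawn independently. In the real data up to 38.1% were called in a population (cortex) and arrays shared structure. The shares below thus check the code and do not give the sensitivity on the real arrays. For salt against standard in one population, 83.3% (cortex) to 92.4% (protophloem) of genes changed 4-fold were recovered, 13.4% (cortex) to 28.4% (stele) of those changed 2-fold, and at most 4.48% (endodermis) of those changed 1.5-fold. For the mean response these shares were 100%, 95.5% and 70.1%, and for the interaction 50.0%, 1.49% and 0%, each in a single simulation. The simulation was rerun with changed seeds, and its first run had recovered more of the 1.5-fold changes of the mean response. Over 10 further seeds the mean response gave 58.2% to 73.1% at 1.5-fold and 94.0% to 98.5% at 2-fold, less at 1.5-fold than in that first run. Alternatives fixed beforehand were offsets of 1 and 64, no filter, a 60th percentile filter, quantile normalization, the replicate number in the model, a 2-fold threshold, each population's own 6 arrays, and leaving out each array in turn. Added after seeing the data were the log2 GAPDH 5'/3' ratio and the log2 cre spike-in signal of each array as covariates, fits on replicates 1 and 2, and fits without the 6 epidermis arrays.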

Results

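Transcript levels were measured on 36 ATH1 arrays in 6 populations of Arabidopsis thaliana root cells, each isolated by fluorescence-activated sorting of protoplasts from a line that carries GFP in a defined part of the root. The reporters mark the epidermis with the lateral root cap (WER::GFP), the columella (PET111), the cortex (CORTEX), the endodermis with the quiescent centre (SCR::GFP), the stele (WOL::GFP) and the protophloem (S32). Roots of seedlings 6 days old were kept on standard medium or moved to medium with 140 mM NaCl for 1 h before the cell walls were digested, which gives 12 groups of 3 replicate arrays. The study asks how cell identity, which changes along the radial axis of the root, shapes the response to salt. Signals are linear MAS5 values with the same trimmed mean on every array and medians of 62.1 to 95.6, and the small number of arrays per group limits the precision. The labels number the replicates without saying that they came from separate plantings, so the p-values measure the spread between these arrays, which may be technical. Correlations between replicates of a group ranged from 0.862 to 0.988 on the log2 scale, and replicates 1 and 2 were the most alike in 10 of the 12 groups.

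The control probe sets differed between some of the groups compared. The ratio of the 5' to the 3' GAPDH signal, which falls when transcripts are copied less completely, was 1.52 ± 0.163 (SD, n = 3) in epidermis on standard medium and 0.248 ± 0.140 with salt. In cortex the ratio was 0.444 ± 0.0596 on standard medium and 0.150 ± 0.0760 with salt, and in protophloem it was 0.0499 ± 0.0318 and 0.162 ± 0.0880. The log2 ratio thus moved by -2.75, -1.70 and 1.80 in these populations, against -0.23 in columella, -0.28 in endodermis and -0.10 in stele. The actin 5'/3' ratio went from 0.155 to 0.0490 in epidermis, from 0.0476 to 0.129 in cortex and from 0.0686 to 0.0247 in protophloem. In cortex and protophloem it thus moved against the GAPDH ratio. The ubiquitin ratio moved against the GAPDH ratio in cortex (0.211 and 0.259), and with it in epidermis (0.457 and 0.316) and protophloem (0.180 and 0.294). The signal of the cre spike-in, a hybridisation control, moved by 1.24 in cortex and -1.35 in protophloem on the log2 scale.

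Cell identity on standard medium was marked by transcripts at very different levels. In protophloem, AT3G20450 reached a signal of 8488 ± 2603 (SD, n = 3) and the glutathione S-transferase GSTF4 (AT1G02950) 7660 ± 1023, against at most 15.8 and 21.1 as the mean of any other population. Such low signals lie under the 40th percentile of the arrays (32.4 to 66.3), where a fold depends on background and on the offset of 16. AT1G09750, the aspartyl protease gene fixed as the check of the CORTEX reporter, had 2650 ± 413 in cortex and at most 57.0 ± 43.4 elsewhere. AT5G01870 had 2313 ± 1174 in endodermis and at most 43.8 elsewhere, the jasmonate-regulated gene JRG21 (AT3G55970) 2586 ± 1171 in columella and at most 55.4, and AT5G24240 209 ± 118 in stele and at most 16.8. In epidermis AT4G25250 was 17.8-fold above cortex, the next highest population by the mean of log2(signal + 16), while stele replicate 3 had a signal of 441. The cinnamoyl-CoA reductase gene CCR2 (AT1G80820), an enzyme of lignin precursor synthesis, was 25.8-fold enriched in endodermis at 2381 ± 451, against 86.5 ± 55.9 in cortex. Among markers fixed beforehand, the phloem gene OPS (AT3G09070) was highest in protophloem at 72.5 ± 28.3 against 32.2 ± 7.66 in stele, and the stele gene LHW (AT2G27230) was highest in stele at 596 ± 78.0 against 402 ± 125 in endodermis. The stele gene PHV (AT1G30490) had 381 ± 59.5 in stele and 373 ± 41.9 in columella, and the quiescent-centre gene AGL42 (AT5G62165) had 153 ± 23.9 in endodermis and 144 ± 50.8 in protophloem. EN7 (AT4G28100) had 447 ± 78.0 in endodermis and 383 ± 30.1 in cortex.

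Of 17633 probe sets tested, 15083 differed between the 6 populations on standard medium and 12882 with salt (limma moderated F-test, adjusted p under 0.05). Probe sets at least 2-fold above every other population numbered 978 in protophloem, 625 in epidermis, 603 in columella, 456 in endodermis, 390 in cortex and 114 in stele. On the salt arrays they numbered 482, 323, 328, 356, 711 and 94 in that order, more than on standard medium in cortex alone. With salt the same population remained the highest for 92.3% of those of endodermis, 85.4% of cortex, 81.8% of columella, 76.3% of stele, 72.4% of protophloem and 61.1% of epidermis. Over all probe sets tested the shares were 10.7%, 26.0%, 15.8%, 9.04%, 15.99% and 22.4% in that order. Enriched probe sets that passed the salt test fell more often than they rose, in sets picked on the same standard arrays: 566 fell and 9 rose in protophloem, 462 and 10 in epidermis, 128 and 45 in columella, 121 and 44 in cortex, 32 and 4 in stele, and 22 and 9 in endodermis. AT1G09750 fell in cortex to 235 ± 27.2, AT4G25250 fell in epidermis from 2788 ± 255 to 534 ± 140, and AT5G01870 had 2313 ± 1174 and 1956 ± 1466 in endodermis.

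**Figure D1:**
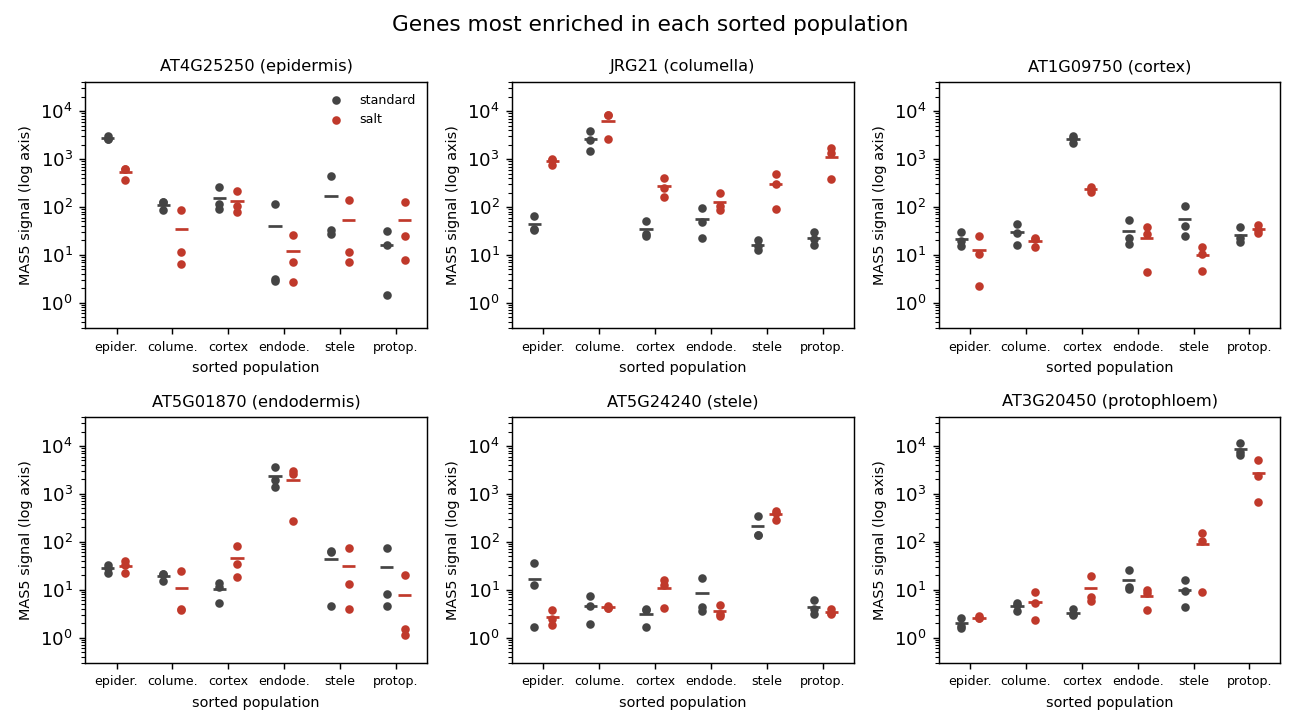
MAS5 signal on a log axis of the gene most enriched in each sorted population on standard medium, with 3 arrays per group as points (grey, standard; red, salt) and group means as bars. AT1G09750 lies near 2650 in cortex on standard medium and near 235 with salt, while AT5G24240 stays highest in stele at 209 and 372.

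When the 6 salt responses were averaged, several genes of protection against drying rose. LEA4-5 (AT5G06760), a late embryogenesis abundant (LEA) protein, rose by 4.53 ± 0.17 (SE, n = 18 arrays against 18) on the log2 scale and passed the test in each population, from 3.18 in protophloem to 5.82 in cortex. The LEA genes AT3G02480 (3.68 ± 0.26), AT3G17520 (3.40 ± 0.20) and AT3G15670 (3.14 ± 0.19) rose as well, as did AT1G04560 (3.52 ± 0.21), the berberine-bridge oxidase gene AT1G30700 (3.07 ± 0.25), the glucosyltransferase gene UGT87A2 (2.83 ± 0.14) and the small heat shock protein gene AT1G52560 (2.79 ± 0.25). AT1G05340 (3.11 ± 0.23) and AT1G68500 (2.86 ± 0.22) completed the 10 largest rises among probe sets with 1 gene and one sign in all populations. In protophloem AT3G02480 (1.05, adjusted p = 0.229), AT1G05340 (1.18, 0.116) and AT1G68500 (0.59, 0.439) did not pass, nor did AT1G52560 in epidermis (1.22, 0.141). The largest falls by the same rule were those of 10 other genes: the RNA-binding protein gene AT1G22330 fell by 2.17 ± 0.13, AT1G78260 by 1.94 ± 0.15, the chalcone isomerase-like gene CHIL, which acts in flavonoid synthesis, by 1.84 ± 0.24, and the beta-expansin gene EXPB1, a cell wall loosening protein, by 1.73 ± 0.19. AT2G04500, AT5G02550, AT2G30930, AT3G54400, AT1G22550 and AT3G02640 fell by 1.66 to 1.82. Of these 10 only AT1G22330 and AT1G22550 passed in each population.

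**Figure D2:**
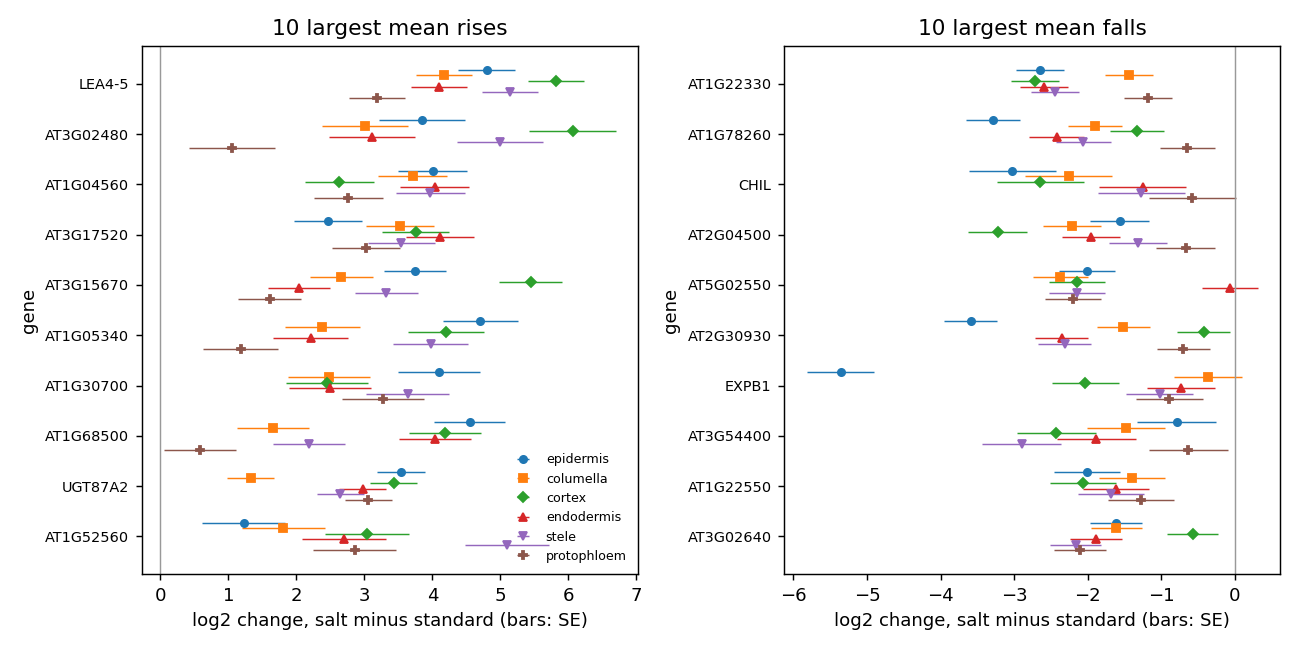
Log2 change with salt in each of the 6 populations (symbols; bars are SE, 3 arrays against 3) for the 10 largest mean rises and falls among probe sets with 1 gene and one sign in all populations. LEA4-5 lies between 3.18 and 5.82 in every population, and EXPB1 lies at -5.36 in epidermis against -2.03 to -0.37 elsewhere.

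For the mean response, 8743 probe sets passed (3670 higher and 5073 lower with salt), of which 933 rose and 303 fell at least 2-fold. The ABA and dehydration list had 3 members measured, LEA4-5, LTI30 (2.56 ± 0.15) and COR47 (1.36 ± 0.13, which by itself passed in epidermis, cortex and stele, there lost without any 1 of 4 arrays), and 3 rose, also adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.123 with an estimated correlation). In the LEA and cold-regulated family, which holds the same 3 genes, so that the calls of the 2 lists are not independent in any contrast, 5 of 7 rose (adjusted p = 5.3e-06, and 0.123 with an estimated correlation). Of 37 UDP-glucosyltransferases, enzymes that attach sugars to hormones and metabolites, 18 rose and 2 fell (adjusted p = 0.00024, and 0.347 with an estimated correlation), with UGT73C7 at 1.84 ± 0.15, UGT73B4 at 1.86 ± 0.16 and UGT76B1 at 1.99 ± 0.20. Of 10 autophagy genes 6 rose, led by ATG8E (1.31 ± 0.16) and ATG8H (1.38 ± 0.18) (adjusted p = 0.0081, and 0.497 with an estimated correlation), while in protophloem 5 fell and 0 rose. Apart from ATG3 this list holds only ATG8 and APG8 genes, so in every contrast its calls are those of related genes and do not cover the pathway. All 6 cytosolic ribosomal protein genes measured fell, also adjusted over the list alone, by 0.68 to 1.27 for the 4 named ones (AT4G10450, AT3G60770, AT5G02870 and AT4G29410; adjusted p = 0.0196, and 0.577 with an estimated correlation). All 5 histone genes fell, led by HTB1 (-0.89 ± 0.15) and HTB2 (-0.76 ± 0.14; adjusted p = 0.0447, and 0.497 with an estimated correlation). Of 69 plastid-encoded genes 24 rose and 0 fell (adjusted p = 0.00011, and 0.723 with an estimated correlation), with 51 lower in protophloem. With the GAPDH ratio, which moved in these populations, as a covariate, the median of the plastid-encoded genes in the mean salt response turned from 0.42 to -0.036.

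Of the other preset lists, 5 of 8 auxin genes rose (6 adjusted over the list alone), with the repressor gene IAA30 at 1.19 ± 0.17 and the auxin-conjugating GH3.3 at 1.08 ± 0.25, without a camera call (adjusted p = 0.0684). In the early stress factor list WRKY6 (1.77 ± 0.23) and the zinc finger gene STZ (0.80 ± 0.14) rose, also adjusted over the list alone, and WRKY53 was at 0.10 ± 0.17. The replication helicase gene PRL (AT4G02060) fell by 0.60 ± 0.13. The ethylene factor EIN3 rose by 0.21 ± 0.09 (adjusted p = 0.0379), a call lost after quantile normalization, on replicates 1 and 2, and in 15 of the 36 refits that left out an array. The heat shock gene ATHSP22.0 rose by 0.66 ± 0.19, a call lost with the GAPDH covariate, and AT3G09440 was at 0.26 ± 0.14; the root hair expansins EXPA18 and EXPA7 were at -0.15 ± 0.30 and -0.08 ± 0.45. Without a camera call, calmodulin-like genes had 4 of 6 higher and 1 lower, beta-glucosidases 5 of 13 higher, bZIP factors 5 higher and 2 lower of 9, WRKY factors 2 of 5 higher, SWEET transporters 4 higher and 1 lower of 11, and tetraspanins 5 higher and 2 lower of 12. Tubulins had 1 higher and 5 lower of 7, RNA polymerase subunits 5 of 12 lower, RALF-like peptides 1 higher and 4 lower of 7, xyloglucan endotransglucosylases 1 higher and 3 lower of 7, and expansins 2 higher and 4 lower of 15. Trichome birefringence-like proteins had 4 of 18 lower, cellulose synthase-like proteins 2 of 7 lower, LSM proteins 2 of 6 lower and CLE peptides 0 of 4 called. Cytochrome P450s (2 higher and 4 lower of 12), glutathione S-transferases (3 and 2 of 13), serine carboxypeptidase-like proteins (5 and 4 of 22), ubiquitin-conjugating enzymes (2 and 2 of 11) and mitochondrion-encoded genes (5 and 2 of 15) went both ways. The median was negative where the test pointed up for the P450s, glutathione S-transferases, carboxypeptidase-like proteins, tetraspanins, ubiquitin-conjugating enzymes and CLE peptides; the mean was positive for the glutathione S-transferases (0.08) and the tetraspanins (0.16).

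Across the 29 lists and 7 contrasts, 45 of 203 camera tests passed. With an estimated correlation 0 passed, with 22 at an unadjusted p under 0.05 and a lowest adjusted p of 0.123, while limma's fry, which tests whether the genes of a list move one way and not against other genes, passed 96.

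The response of each population was then tested as a contrast of 3 salt against 3 standard arrays, with the spread pooled over all 36 arrays. Probe sets that passed numbered 6719 in cortex, 4983 in epidermis, 4469 in stele, 4273 in protophloem, 2503 in columella and 444 in endodermis. The salt and standard arrays did not overlap for 49.3%, 56.0%, 43.1%, 34.9%, 29.5% and 15.6% of the probe sets tested, in that order, where chance gives 10%. The median change of all probe sets was 0.17, 0.07, -0.23, -0.07, -0.23 and -0.08, and quantile normalization moved it by -0.21 in cortex, 0.12 in stele and 0.19 in columella, so that changes of this size in these populations depend on the scaling. For a response against the other 5 populations, the same normalization moved the median by -0.12 in epidermis, 0.18 in columella and -0.25 in cortex.

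**Figure D3:**
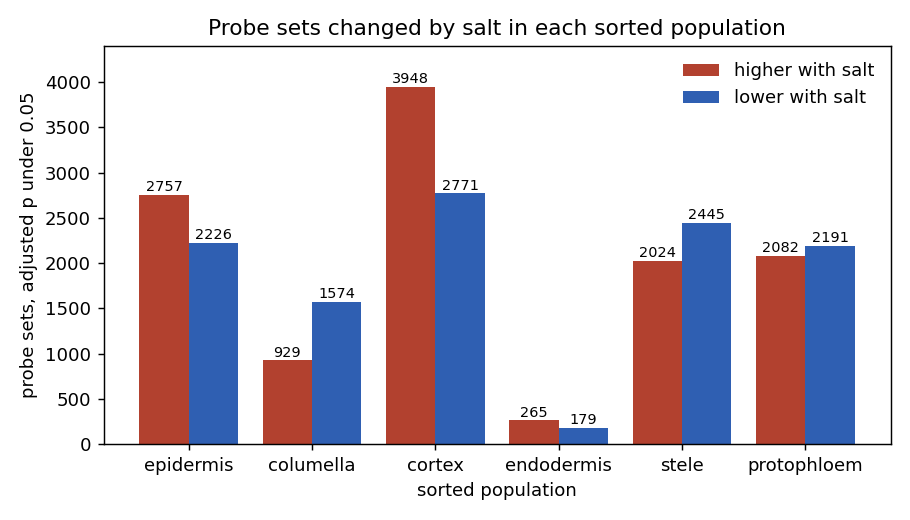
Number of probe sets past an adjusted p of 0.05 in each sorted population (bars from 0; red, higher with salt; blue, lower), 3 salt against 3 standard arrays. Cortex has 3948 higher and 2771 lower, and endodermis 265 and 179.

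In epidermis with lateral root cap, the cell wall gene EXPB1 fell from a signal of 2025 ± 243 (SD, n = 3) to 43.2 ± 41.8, a log2 change of -5.36 ± 0.46 (SE; adjusted p = 8.0e-10). LEA4-5 rose from 20.2 ± 6.79 to 982 ± 86.8. The dehydrin gene COR47 rose by 3.56 ± 0.31, LTI30 by 3.04 ± 0.38, and CHX20 (AT3G53720), a cation/proton exchanger, by 4.64 ± 0.52. AT1G05340 (4.70), AT1G68500 (4.55), AT4G18425 (4.47) and AT1G21680 (4.45) rose, as did the plastid ribosomal protein genes rpl16 (5.04 ± 0.60) and rpl20 (4.66 ± 0.81). The kinase-related gene AT3G46280 (-4.58), GSTU28 (-3.62), AT2G30930 (-3.59) and AT2G39130 (-3.46) fell. Of 15 expansins 4 fell and 0 rose, among them EXPA4 (-2.68 ± 0.35) and EXPA8 (-2.07 ± 0.74; camera adjusted p = 0.0447, and 0.453 with an estimated correlation). Of 37 UDP-glucosyltransferases 16 rose, led by UGT87A2 (3.54 ± 0.35), UGT72E1 (2.30 ± 0.32), UGT76C2 (2.59 ± 0.38) and UGT73C7 (2.44 ± 0.38; adjusted p = 0.00041, and 0.374 with an estimated correlation). The ABA and dehydration list (3 of 3 higher, also adjusted over the list alone) and the LEA family (4 of 7) were called with adjusted p = 1.8e-05 and 3.6e-05, and 0.123 and 0.153 with an estimated correlation. Of 10 autophagy genes 6 rose, ATG8F by 2.31 ± 0.29, ATG8E by 2.20 ± 0.39 and ATG8H by 2.03 ± 0.44 (adjusted p = 0.0055, and 0.497 with an estimated correlation). Of the auxin list GH3.3 (2.92 ± 0.61), GH3.1 (1.64 ± 0.45) and IAA30 (1.49 ± 0.42) rose, also adjusted over the list alone, without a camera call, and STZ rose by 1.35 ± 0.34.

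Plastid-encoded genes rose in epidermis in 41 of 69 cases with 0 lower, at a median log2 change of 1.99 (camera adjusted p = 8.6e-13, and 0.544 with an estimated correlation), beside the fall of the GAPDH ratio from 1.52 to 0.248. With that ratio as a covariate their median turned to -0.44 and the calls of rpl20, GSTU28, STZ and GH3.1 were lost. This fit calls 2957 probe sets in epidermis, 2035 of them among the 4983 (2757 higher, 2226 lower) of the fit without it. On its own 6 arrays the population gave 8046 calls. The response of epidermis differed from the mean of the other 5 populations for 2492 probe sets (1466 higher, 1026 lower), or 977 higher and 1046 lower after quantile normalization. The largest differences were those of rpl16 (4.89 ± 0.65), the photosystem I gene psaB (4.40 ± 0.45) and rpl20 (4.10 ± 0.88), and on the negative side EXPB1 (-4.35 ± 0.50), the small heat shock protein gene AT5G51440 (-3.93 ± 0.51) and AT3G46280 (-3.90 ± 0.62). Without standard replicate 1 or 2, or salt replicate 1 or 2, this count was 1628, 1490, 1498 and 1435, and the difference of rpl20 was 0.41 with the GAPDH covariate, no longer past the test.

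In columella, LEA4-5 rose by 4.17 ± 0.42 and the dehydrin gene LTI30 (AT3G50970) from 654 ± 199 to 8378 ± 2916 (SD, n = 3; log2 change 3.63 ± 0.38, adjusted p = 1.5e-07), while the dehydrin gene COR47 was at 11408 ± 3184 and 13868 ± 3885 and did not pass (0.28 ± 0.31). AT5G66780 (3.91 ± 0.64), AT3G55720 (3.81 ± 0.66), AT1G04560 (3.71 ± 0.51), AT3G17520 (3.52 ± 0.50), AT3G17110 (3.36 ± 0.54) and the cysteine protease gene AT4G16190 (3.19 ± 0.41) rose. The auxin-conjugating gene GH3.17 (AT1G28130) fell from 3679 ± 277 to 333 ± 86.9 (-3.43 ± 0.56), and WES1, another GH3 enzyme, by 2.23 ± 0.33. The multicopper oxidase-like gene sks15 (-3.13 ± 0.69), the endoglucanase gene GH9B6 (-2.94 ± 0.51), AT1G48070 (-2.92 ± 0.46) and AT1G50720 (-2.89 ± 0.42) fell, as did WRKY53 (-1.87 ± 0.41). In the ABA and dehydration list 2 of 3 rose, also adjusted over the list alone, and in the LEA family 3 of 7 (adjusted p = 1.5e-05 and 8.0e-05, and 0.123 and 0.182 with an estimated correlation). Of the UDP-glucosyltransferases 5 of 37 rose and of the autophagy genes 2 of 10, ATG8H (1.89 ± 0.44) and ATG8E (1.40 ± 0.39; adjusted p = 0.0045 and 0.0058, and 0.453 and 0.497 with an estimated correlation). The plastid-encoded list was also called higher, at a median of 0.24 with 0 of 69 members past the test (adjusted p = 0.0051, and 0.781 with an estimated correlation). Of the 2503 calls 929 were higher and 1574 lower, and after quantile normalization 1031 were higher and 822 lower. The count was 1327 without standard replicate 1, 1290 without standard replicate 2, 1043 without salt replicate 1, 629 without salt replicate 2 and 4048 without salt replicate 3. It was 6047 on replicates 1 and 2 and 539 on the population's own 6 arrays.

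The columella response differed from that of the other populations for 429 probe sets (63 higher, 366 lower), or 113 higher and 238 lower after quantile normalization. ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, rose in columella from 3.80 ± 1.78 to 147 ± 23.1 (SD, n = 3), a log2 change of 3.03 ± 0.25 against 1.01 in epidermis, -1.78 in cortex and -0.10 to 0.29 in the others. AT2G44260 and AT4G35070 were also higher (differences of 2.30 ± 0.41 and 2.20 ± 0.51; with an offset of 1 they were 2.26 and 2.36, with adjusted p = 0.0858 and 0.0528), and AT3G53980, a lipid-transfer-type protein gene (-4.02 ± 0.65), GH3.17 (-3.62 ± 0.62) and AT1G50720 (-3.07 ± 0.46; with an offset of 1 it was -3.61, with adjusted p = 0.0627) lower. The count was 159, 188, 125 and 87 without standard replicate 1, standard replicate 2, salt replicate 1 and salt replicate 2, and 1211 without salt replicate 3.

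In cortex the LEA gene AT3G02480 rose from 16.1 ± 11.4 to 2589 ± 1719 (SD, n = 3), a log2 change of 6.06 ± 0.63 (adjusted p = 4.7e-08), LEA4-5 from 52.1 ± 14.4 to 4358 ± 2393 (5.82 ± 0.42), AT3G15670 by 5.44 ± 0.46, and the seed maturation protein gene AT2G21820 by 4.83 ± 0.51. AT1G24600 (5.43 ± 0.75), the peptide gene RALFL32 (4.53 ± 0.43), AT1G05340 (4.20 ± 0.55) and AT1G68500 (4.18 ± 0.53) rose as well. The sugar-transporter-like gene AT3G05150 fell from 2545 ± 25.1 to 92.1 ± 44.5 (-4.67 ± 0.47), and AT5G62210 (-3.99 ± 0.44), AT1G76470 (-3.58 ± 0.30), the transcription factor gene BZIP61 (-3.40 ± 0.57) and the reporter gene AT1G09750 (-3.40 ± 0.36) fell. Of 11 SWEET sugar transporters 9 rose, among them SWEET2 (1.91 ± 0.36), SWEET1 (1.62 ± 0.30) and SWEET13 (1.51 ± 0.28), and 1 fell, chosen for mention after its value was seen, SWEET16 (-1.27 ± 0.29; adjusted p = 0.0162, and 0.453 with an estimated correlation). Of 7 tubulins 4 fell, TUB9 (-1.07 ± 0.25), TUA6 (-1.61 ± 0.44), TUB5 (-2.08 ± 0.57) and TUB7 (-1.20 ± 0.33), and 1 rose (adjusted p = 0.0477, and 0.497 with an estimated correlation). In the ABA and dehydration list 3 of 3 rose, also adjusted over the list alone, and in the LEA family 6 of 7, with LEA18 at 3.72 ± 0.41 (adjusted p = 0.00084 and 3.6e-05, and 0.236 and 0.153 with an estimated correlation). STZ rose by 1.86 ± 0.34, and of the auxin list IAA29 (2.09 ± 0.45), LBD16 (1.44 ± 0.40) and IAA30 (1.38 ± 0.42) rose, also adjusted over the list alone, without a camera call. The call of IAA30 was lost after quantile normalization, without standard replicate 2 and without salt replicate 1.

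Organelle-encoded transcripts rose in cortex as well, beside the fall of the GAPDH ratio from 0.444 to 0.150 and the rise of the cre spike-in signal from 4916 ± 219 to 12735 ± 6396 (SD, n = 3). Of 69 plastid-encoded genes 50 rose (median 2.00, adjusted p = 2.8e-12, and 0.570 with an estimated correlation), and of 15 mitochondrion-encoded genes 11 rose, with nad1 at 3.58 ± 0.53 and nad4 at 3.23 ± 0.67 (adjusted p = 0.0016, and 0.580 with an estimated correlation). With the GAPDH ratio or the cre signal as a covariate 3193 and 3938 probe sets passed in cortex, of which 2868 and 3437 were among the 6719 of the fit without it. These 6719 were 3948 higher and 2771 lower, and quantile normalization gave 2403 higher and 3291 lower. Compared with the other populations, 5967 probe sets differed (3915 higher, 2052 lower), or 1734 higher and 2356 lower after quantile normalization, and 3658 and 3209 with the covariates. RALFL32 (4.33 ± 0.47), AT2G07673 (4.06 ± 0.65) and AT2G07739 (3.96 ± 0.83) were higher, and AT3G55720 (-4.56 ± 0.73), AT3G05150 (-3.74 ± 0.51) and AT5G62210 (-3.51 ± 0.49) lower. AT2G07673 and AT2G07739 changed by 3.57 and 3.41 in cortex, and by as low as -3.05 and -2.56 in another population. Sequences were not analysed, so their probe sets may also read organelle-encoded transcripts, which rose in cortex too, and this was not tested.

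In endodermis with quiescent centre, fewer probe sets passed than in any other population. AT3G17520, a LEA gene, rose by 4.11 ± 0.50 on the log2 scale (SE, 3 arrays against 3; adjusted p = 3.8e-06), LEA4-5 from 226 ± 54.3 (SD) to 4210 ± 1288 (4.10 ± 0.42), and the serine-rich salt-response gene SIS (AT5G02020) from 187 ± 21.7 to 2045 ± 974 (3.24 ± 0.32). AT1G68500 (4.04 ± 0.53), AT1G04560 (4.03 ± 0.51), AT5G66780 (3.35 ± 0.64), UGT87A2 (2.98 ± 0.35) and LTI30 (1.86 ± 0.38) rose, and so did AT3G02480 (3.11 ± 0.63), except when salt replicate 2 was left out. The wall-remodelling gene XTH16 (AT3G23730) fell from 976 ± 359 to 88.6 ± 81.8 (-3.44 ± 0.44), and AT1G22330 (-2.60 ± 0.32), AT4G01140 (-2.53 ± 0.34) and AT3G45680 (-2.45 ± 0.47) fell. AT1G19900 was at -2.69 ± 0.57, a call lost without standard replicate 3 or salt replicate 1. In the ABA and dehydration list 2 of 3 rose (3 adjusted over the list alone) and in the LEA family 2 of 7 (adjusted p = 2.1e-07 and 9.7e-07, and 0.123 and 0.123 with an estimated correlation). The auxin list was called higher with 0 of 8 members past the test over all genes and 1 adjusted over the list alone, IAA30 being at 1.32 ± 0.42 (adjusted p = 0.0185, and 0.422 with an estimated correlation). The autophagy list was called higher (median 0.31) and the trichome birefringence-like proteins lower (median -0.54), both with 0 members past the test over all genes (adjusted p = 0.0198 and 0.0162, and 0.510 and 0.465 with an estimated correlation). The 444 calls were 265 higher and 179 lower. The count was 242, 236, 239 and 222 without standard replicate 1, standard replicate 2, salt replicate 1 and salt replicate 2, and 911 without salt replicate 3. It was 1968 on replicates 1 and 2 and 172 on the population's own 6 arrays. Against the other 5 populations 54 probe sets differed (8 higher, 46 lower). Highest were AT5G67430 (2.36 ± 0.54), AT5G02550 (2.11 ± 0.41) and AT1G60730 (2.01 ± 0.43), and lowest AT5G40020 (-3.32 ± 0.70), AT4G18425 (-3.10 ± 0.61) and AT1G70500 (-3.09 ± 0.63). The calls of AT5G67430 (3.53, adjusted p = 0.177), AT1G60730 (2.25, 0.188) and AT1G70500 (-4.42, 0.0580) were lost with an offset of 1. That of AT5G40020 was lost with an offset of 64 (-2.16, 0.0506) and that of AT5G67430 without the filter (2.36, 0.0601). Those of AT1G60730 (2.14, 0.0552), AT5G40020 (-3.17, 0.0575) and AT1G70500 (-2.89, 0.0575) were lost after quantile normalization. Without standard replicate 1, 2 or 3, or salt replicate 1 or 2, the count of 54 became 4, 2, 12, 5 and 4, and most of the 6 calls were lost. Without salt replicate 3 it was 248.

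In stele, LEA4-5 rose from 32.6 ± 26.9 to 1589 ± 438 (SD, n = 3; log2 change 5.14 ± 0.42, adjusted p = 7.5e-10), the small heat shock protein gene AT1G52560 by 5.09 ± 0.61, AT3G02480 by 5.00 ± 0.63 and the lignin gene CCR2 from 49.3 ± 72.6 to 867 ± 309 (4.28 ± 0.53). AT1G05340 (3.97 ± 0.55), AT1G04560 (3.96 ± 0.51), AT5G16010 (3.83 ± 0.63) and the hypoxia-responsive gene AT3G10020 (3.73 ± 0.41) rose. The defensin-like gene PDF2.5 (AT5G63660) fell from 1143 ± 659 to 111 ± 24.1 (adjusted p = 4.0e-05). The aspartyl protease gene AT3G54400 (-2.90 ± 0.54), the thaumatin-like genes AT1G73620 (-2.73 ± 0.53) and ATLP-1 (-2.58 ± 0.43) and AT3G56480 (-2.47 ± 0.42) fell as well. Of 8 auxin genes 5 rose, also adjusted over the list alone, with the lateral-root factor LBD16 at 2.06 ± 0.40 and IAA29 at 1.69 ± 0.45 (adjusted p = 0.0072, and 0.329 with an estimated correlation). Among the 5, the call of IAA30 was lost with an offset of 1 and in each of 6 refits that left out a stele array. That of GH3.3 was lost in 3 such refits. Of the early stress factors WRKY6 (2.66 ± 0.57) and STZ (1.46 ± 0.34) rose, also adjusted over the list alone (adjusted p = 0.0192, and 0.453 with an estimated correlation). Calmodulin-like calcium sensors rose in 3 of 6 cases, CML37 by 3.43 ± 0.47, CML38 by 3.23 ± 0.59 and CML23 by 1.64 ± 0.41 (adjusted p = 0.0155, and 0.247 with an estimated correlation). Beta-glucosidases rose in 5 of 13, led by BGLU25 (2.47 ± 0.36; adjusted p = 0.0250, and 0.219 with an estimated correlation). The bZIP factors rose in 4 of 9, led by BZIP28 (1.05 ± 0.21; adjusted p = 0.0477, and 0.361 with an estimated correlation). RNA polymerase subunits fell in 4 of 12 cases, NRPC1 by 0.89 ± 0.24 (adjusted p = 0.0192, and 0.570 with an estimated correlation).

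In stele the ABA and dehydration list (3 of 3 higher, also adjusted over the list alone), the LEA family (5 of 7) and the autophagy genes (4 of 10, ATG8H by 2.33 ± 0.44) were called with adjusted p = 3.6e-05, 0.00027 and 0.00026, and 0.142, 0.222 and 0.422 with an estimated correlation. Of 37 UDP-glucosyltransferases 9 rose and 2 fell, with UGT73B4 at 3.33 ± 0.40 (adjusted p = 0.0075, and 0.477 with an estimated correlation), and their median of 0.32 turned to -0.02 without standard replicate 1. The 4469 calls in stele were 2024 higher and 2445 lower. They numbered 2254, 2340 and 2245 without standard replicate 1, standard replicate 2 and salt replicate 2, and 7196 on replicates 1 and 2. The response of stele differed from the others for 131 probe sets (79 higher, 52 lower), or 137 higher and 35 lower after quantile normalization. The largest differences were those of AT1G52560 (2.77 ± 0.67), CCR2 (2.74 ± 0.58) and AT4G39675 (2.52 ± 0.58) on the positive side and PDF2.5 (-2.73 ± 0.52), AT3G56480 (-2.42 ± 0.46) and AT5G45210 (-1.98 ± 0.37) on the negative. With an offset of 1, AT1G52560 (3.57, adjusted p = 0.0965), CCR2 (3.24, 0.0822), AT4G39675 (2.34, 0.130) and AT3G56480 (-2.44, 0.0557) were not called. The call of AT5G45210 was lost with an offset of 64 (-0.89, 0.0527) and that of AT1G52560 without the filter (2.77, 0.0534). In place of 131, the count was 10, 3, 4 and 1 without standard replicate 1, standard replicate 2, salt replicate 1 and salt replicate 2, so that these calls rest on each of those arrays, and 1864 without standard replicate 3.

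In protophloem the jasmonate-regulated gene JRG21 rose from 22.6 ± 7.48 to 1131 ± 663 (SD, n = 3), a log2 change of 4.67 ± 0.51 (adjusted p = 7.0e-07), the transcription factor gene WRKY6 from 28.6 ± 33.6 to 516 ± 97.8 (3.81 ± 0.57), the kinase gene AT5G47070 by 3.68 ± 0.43 and the salt-tolerance gene SAT32 (AT1G27760) by 3.27 ± 0.41. AT5G02230, AT4G24110 (3.40 ± 0.45), AT5G12010 (3.37 ± 0.45), AT1G30700 (3.27 ± 0.60) and LEA4-5 (3.18 ± 0.42) rose, and the remorin-family gene AT4G00670 fell from 1824 ± 564 to 152 ± 111 (-3.65 ± 0.46). Of 37 UDP-glucosyltransferases 13 rose and 1 fell, with UGT73D1 at 3.02 ± 0.51 and UGT73B5 at 3.21 ± 0.55 (adjusted p = 1.5e-05, and 0.219 with an estimated correlation). Of 10 autophagy genes 5 fell and 0 rose, APG8A by 1.87 ± 0.40 and ATG8D by 1.44 ± 0.31 (adjusted p = 0.0170, and 0.510 with an estimated correlation). In the ABA and dehydration list 2 of 3 rose, also adjusted over the list alone (adjusted p = 0.0155, and 0.453 with an estimated correlation), and GH3.1 of the auxin list rose by 2.39 ± 0.45, in a list with a median of -0.28 and a mean of 0.40. The CLE peptides were called lower with 1 of 4 past the test over all genes, CLE26 (-2.91 ± 0.37; adjusted p = 0.0279, and 0.422 with an estimated correlation).

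Of 69 plastid-encoded genes 51 fell and 0 rose in protophloem (median -1.96, adjusted p = 2.2e-17, and 0.497 with an estimated correlation), and of 15 mitochondrion-encoded genes 11 fell (median -1.99, adjusted p = 2.1e-06, and 0.465 with an estimated correlation). Of the plastid-encoded genes, the photosystem genes psbT (-3.91 ± 0.61) and psaC (-3.68 ± 0.58), petN (-3.58 ± 0.61) and ndhE (-3.80 ± 0.79, a call lost with the GAPDH covariate, and with the cre covariate at -1.57, adjusted p = 0.0584) fell most. Here the GAPDH ratio rose from 0.0499 to 0.162 and the cre signal fell from 18629 ± 9788 to 7009 ± 2269 (SD, n = 3). With the GAPDH ratio or the cre signal as a covariate 2287 and 2842 probe sets passed, 1769 and 2079 of them among the 4273 (2082 higher, 2191 lower) of the fit without it. The count was 2253 without standard replicate 2, 2694 without salt replicate 1 and 1887 on the population's own 6 arrays. Against the other 5 populations 3587 differed (1782 higher, 1805 lower), but 372 with the GAPDH covariate, 1035 with the cre covariate and 1887 without standard replicate 2. The most negative were psbN (-4.79 ± 0.98), ndhE (-4.77 ± 0.87) and psbT (-4.68 ± 0.67). The most positive were MSRB9 (3.17 ± 0.68), a methionine sulfoxide reductase, XTH19 (3.05 ± 0.66) and the acid phosphatase-like gene AT5G44020 (2.99 ± 0.87). With the GAPDH covariate the call of MSRB9 was kept, and XTH19 was at 2.64 (adjusted p = 0.139) and psbT at -1.61 (adjusted p = 0.108). The differences of psbN, ndhE and AT5G44020 shrank to -0.94, -0.69 and 0.28 and were not called.

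**Figure D4:**
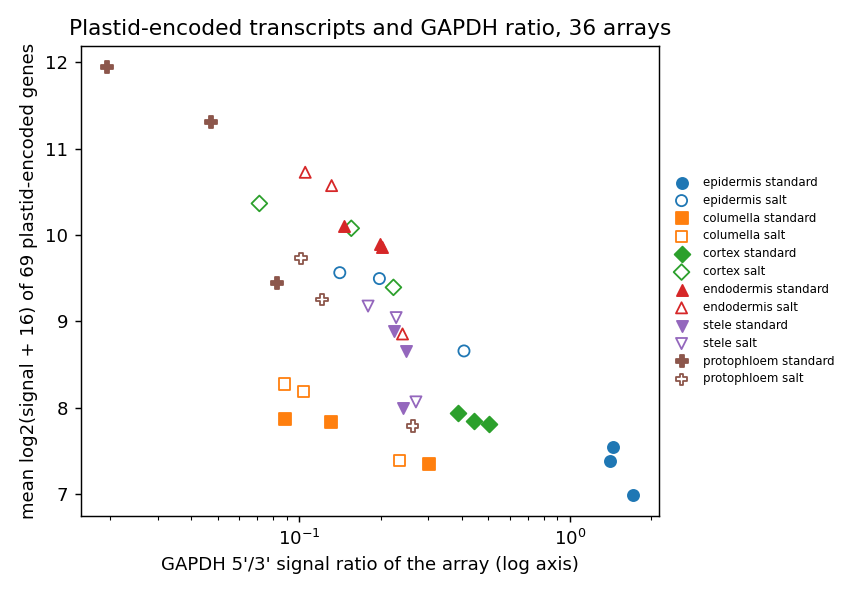
Mean log2(signal + 16) of 69 plastid-encoded genes against the GAPDH 5'/3' signal ratio (log axis) for 36 arrays, by population (symbol) and medium (filled, standard; open, salt). Group means run from 7.31 in epidermis on standard medium, where the ratio is 1.52, to 10.90 in protophloem on standard medium, where it is 0.0499. Populations differ at a like ratio: with salt, columella lies at 7.95 (ratio 0.142) and cortex at 9.95 (0.150).

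Whether the responses differ between populations was tested directly, and 8215 probe sets passed the interaction F-test. Among probe sets with 1 gene, ICL had the largest F (39.4): it rose by 3.03 in columella and 1.01 in epidermis and fell by 1.78 in cortex. AT4G32030 (F = 35.2) changed by -2.27 in epidermis, 2.22 in stele and 1.82 in protophloem. AT1G53035 (F = 28.5) was at -2.95 in protophloem and -1.40 in columella, AT2G31940 (F = 28.1) at 4.13 in epidermis against -0.39 in protophloem, and the COPII coat gene AT3G63460 (F = 24.7) at -3.03 in epidermis against -0.68 to 0.15 elsewhere. RALFL32 (F = 23.1) rose in cortex by 4.53, and the plastid genes psaB (F = 22.2) and rpoA (F = 21.8) were at 4.39 and 3.27 in epidermis. AT1G66890 (F = 21.0) was at 1.69 in cortex and -2.95 in protophloem, and AT3G07890 (F = 20.9) at -2.02 in epidermis and -1.17 in cortex. With the GAPDH or the cre covariate 5926 and 5901 probe sets passed, and 5042 without the 6 epidermis arrays.

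At least 1 population had a call for 12949 probe sets. Of these, 4406 rose in exactly 1 population and 73 in all 6, among them 30 with a gene name such as LEA4-5, LTI30, SIS, UGT87A2, UGT73C7, the aldehyde dehydrogenase gene ALDH7B4 and the F-box gene SKP2A. Falls in all 6 numbered 7, of which the 3 named were AT1G22330, AT1G22550 and AT5G09850. These 3 names and ALDH7B4 and SKP2A were chosen after their values were seen. Higher in one population and lower in another were 1828, of which 1827 passed the interaction test, as opposite calls from the same fit nearly must. Columella and stele had the most similar responses across genes (Pearson r = 0.645 and Spearman rho = 0.597 over 17633 probe sets, which are not independent replicates; 15 pairs compared). They shared 635 rises where independent lists of that size share 107 and 660 falls where they share 218. Cortex and protophloem had r = -0.0865 and rho = -0.134, and shared 457 rises where independent lists share 466, with 1024 opposite calls against 818. The other 14 pairs lay between 0.205 and 0.645.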

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

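The tests of a response shared with other cell types and of protophloem cells in the cortex sorts were chosen only after the results they measure were seen, as were the covariate fits.

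Responses that differed between populations by a direct test were picked out for a closer look. The interaction F-test passed for 8215 probe sets, and each response against the mean of the other 5 passed for 2492 in epidermis, 429 in columella, 5967 in cortex, 54 in endodermis, 131 in stele and 3587 in protophloem. Higher in one population and lower in another, with the interaction, were 1827 probe sets, a count to which the interaction test adds little, since opposite calls from the same fit nearly always pass it. Single genes were ICL (F = 39.4), AT4G32030 (F = 35.2), AT1G53035 (F = 28.5), AT2G31940 (F = 28.1), AT3G63460 (F = 24.7), RALFL32 (F = 23.1), psaB (F = 22.2), rpoA (F = 21.8), AT1G66890 (F = 21.0) and AT3G07890 (F = 20.9).

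For most of these counts the real assignment of arrays gave more calls than every other split drawn. For the mean response, the interaction and each response against the rest, a draw shuffled salt and standard within every population at once. For the differences on each medium, a draw shuffled the populations within a medium. Shuffling the media removes the shared salt response along with any difference. For the interaction and the comparisons with the rest it thus cannot test whether the responses differ. The smallest share that 100 splits can give is 1 of 100. Chance assignment is thus made less likely, but is not excluded, for the mean response and for the differences between populations on each medium. The margin was narrow for epidermis (2492 against 2445) and columella (429 against 402) compared with the rest. In 100 splits, the real one included, 1 gave as many calls for the mean response (8743; highest other 1791), the interaction (8215; 2093), the comparisons of epidermis (2492; 2445), columella (429; 402), cortex (5967; 4086), endodermis (54; 31) and protophloem (3587; 2759) with the rest, and the differences between populations on standard medium (15083; 1373) and with salt (12882; 329). For stele against the rest, 4 of 100 splits gave as many as the real 131, and the highest other gave 2936. A draw can keep or wholly swap the labels of stele while those of the other populations are scrambled. Its count then includes the response that stele shares with them. The splits behind these counts were not examined, so the 2936 is not read further. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: 1 of 10, the real one, gave as many in each population, with 4983 in epidermis (highest other 0), 2503 in columella (588), 6719 in cortex (11), 444 in endodermis (3), 4469 in stele (298) and 4273 in protophloem (71).

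Organelle-encoded transcripts, 84 probe sets, rose in epidermis and cortex and fell in protophloem, 3 populations in which the GAPDH ratio moved. Within groups, over 36 arrays, the deviation of their mean from its group mean followed that of the log2 GAPDH ratio (Pearson r = -0.840, permutation p = 1e-05, the smallest the 100000 resamples can give, adjusted p = 2e-05 over 2 relations; Spearman rho = -0.821; r = -0.835 without the 2 farthest arrays) and of the log2 cre signal (r = 0.750, permutation p = 6e-05, adjusted p = 6e-05, rho = 0.764, r = 0.739). A more 3'-biased amplification or a lower yield of labelled RNA may thus account for part of the pattern. The control ratios disagree on such a bias in cortex, where actin and ubiquitin moved against GAPDH, and in protophloem, where actin did. With the GAPDH ratio and the cre signal as covariates the mean organelle change was -0.31 ± 0.60 (SE) in epidermis, 0.57 ± 0.35 in cortex and -0.41 ± 0.36 in protophloem. Without them it was 1.76, 2.00 and -1.92 (SE 0.52) in that order. With these covariates the smallest median in the original direction was -0.424, in epidermis. A change of organelle transcripts with salt that differs between populations is thus neither shown nor excluded, since the covariates moved with the medium in these populations and the standard error exceeds the value in epidermis. Of the probe sets called without covariates, 15 of 61 in cortex, 10 of 62 in protophloem and 4 of 45 in epidermis were called in the same direction with both, and the covariate fit made 1 new call in columella and 1 in stele.

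In epidermis the salt response came with a fall of the GAPDH ratio on the log2 scale of -2.75. If that bias set the response, its difference from the other populations should follow, across genes, the slope on the ratio within the other 10 groups. The r was -0.122, a value that 3 of 100 draws reached or passed on the low side, the real one included. Shuffled ratios gave r from -0.176 to 0.145, so that a contribution may exist but is not shown, and r this small leaves its size open. If the response is one that other populations share, it should follow the mean response of columella, endodermis and stele, whose ratio moved least: r was 0.549 across genes, which are not independent. These values are consistent with a shared salt response in epidermis beside a part of unknown size that cannot be told apart from array quality, because each epidermis group has one range of the ratio.

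The cortex and protophloem responses had r = -0.0865 across genes, the only negative one of 15 pairs. Cells of the protophloem in the cortex salt sorts are argued against as the source of the whole rise: the median rise of 0.77 of protophloem-enriched probe sets in cortex over that of all probe sets would need 8.58% such cells, and the 20 most enriched would then have a median signal of 808, where 56.2 was measured, from 8.34 on standard medium, with a median ratio of 0.0683 and a highest of 0.146. With the salt-treated protophloem as the source the median ratio was 0.0813. A smaller share of such cells is not excluded. The protophloem-enriched probe sets were picked on the same standard arrays against which the rise in cortex was measured. That choice can raise the 0.77, and with it the share of cells and the expected signal. With both quality covariates r was 0.0039, so that array quality shared by cortex salt and protophloem standard arrays, both with low GAPDH ratios, may be behind the sign. The actin ratio moved against the GAPDH ratio in both populations, so the controls do not agree on this quality. It cannot be told apart from opposite biology, since r lay between -0.126 and -0.028 when single arrays were left out. The r was -0.0661 without organelle-encoded probe sets, -0.0305 after quantile normalization and -0.0189 on replicates 1 and 2.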

How the results depend on the processing

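The fits on replicates 1 and 2, those with the GAPDH or cre covariate and those without the epidermis arrays were chosen after seeing the data; the other alternatives were fixed before. Of the 16 counts of calls, all stayed within 1.5 times without the filter, 15 did with an offset of 64, the stricter filter and quantile normalization, and 14 with an offset of 1. Compared with the other populations, endodermis moved from 54 to 35 (offset 1) and 28 (quantile normalization), and stele from 131 to 48 (offset 1), 269 (offset 64) and 87 (stricter filter, which tests fewer probe sets). On replicates 1 and 2 the counts rose to 6047 in columella, 1968 in endodermis and 7196 in stele, and against the other 5 to 3973 in epidermis, 2422 in columella, 1531 in endodermis and 2656 in stele. The replicate 3 arrays lie apart, 11 of 12 on the negative side of the leading component of the within-group deviations (19.7%) and 22 of the 24 others on the positive. With the GAPDH covariate the counts were 2957 in epidermis, 3193 in cortex and 2287 in protophloem, and against the other 5 they were 671 in columella, 3658 in cortex, 97 in endodermis, 252 in stele and 372 in protophloem. With the cre covariate they were 3938 in cortex and 2842 in protophloem, and against the other 5 they were 681 in columella, 3209 in cortex, 86 in endodermis, 245 in stele and 1035 in protophloem. A 2-fold threshold left 1236 for the mean response, own arrays gave 8046 in epidermis, 539 in columella, 172 in endodermis and 1887 in protophloem, and the interaction had 5042 without epidermis. List tests passed 0 times with an estimated correlation and 96 times with fry, against 45.

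Leaving out single arrays gave 3634 to 4506 calls in epidermis, 629 to 4048 in columella, 4672 to 7715 in cortex, 222 to 911 in endodermis, 2245 to 5798 in stele and 2253 to 4041 in protophloem, with the low ends without salt replicate 2 (columella, cortex, endodermis, stele) or standard replicate 2 (epidermis, protophloem). For each response against the others the ranges were 1435 to 2444 in epidermis, 87 to 1211 in columella, 4204 to 6842 in cortex, 2 to 248 in endodermis, 1 to 1864 in stele and 1887 to 3593 in protophloem. They were 8276 to 9042 for the mean response, 6898 to 9673 for the interaction, 14451 to 15322 between populations on standard medium and 11607 to 13327 with salt. The arrays whose removal moves a count by more than 1.5 times are named with the counts in the results above. Reversed values were the median of the UDP-glucosyltransferases in stele without stele standard replicate 1 (-0.016, against 0.40 without standard replicate 3), and with the GAPDH covariate that of the plastid-encoded genes in epidermis (-0.44) and in the mean response (-0.036). The cause was not tested in any of these cases. Among named genes, 23 weakened with the GAPDH covariate, 14 with an offset of 1, 11 with the cre covariate and 10 after quantile normalization.

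Arrays share replicate numbers, but the numbers do not pair all of them: deviations correlated over 0.1 in 8 of 18 pairs, and 7 of 18 did best with their own number. Replicate 3 shared a structure in epidermis (r = 0.145), columella (0.3001), endodermis (0.336) and stele (0.445), each best with its own number, and not in cortex (-0.0626) or protophloem (-0.115). With the replicate number as a block the stele count against the other 5 rose from 131 to 263, and the other 15 counts stayed within 1.5 times.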

Other observations

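The hypothesis on cell-type-enriched genes was stated before its test was run, and the choice of genes on salt or on both media was added after its result was seen; genes in the first paragraph were taken by the list rule from lists described only in part above.

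Several families were split within one population. In protophloem the glutathione S-transferases GSTU25 (2.50 ± 0.32, SE) and GSTU22 (2.38 ± 0.45) rose while GSTU18 (-2.16 ± 0.41) and GSTF4 (-2.07 ± 0.42), one of its most enriched genes, fell: 3 of 13 rose and 4 fell. There the wall gene XTH19 rose by 3.00 ± 0.60 while XTH32 (-1.36 ± 0.35), XTH16 (-1.67 ± 0.44) and XTH33 (-1.37 ± 0.40) fell. In stele the expansin-like genes EXLA3 (2.69 ± 0.61), EXLB1 (1.98 ± 0.48) and EXLA1 (2.01 ± 0.55) rose and the expansin EXPB3 (-1.08 ± 0.28) fell, with 3 of 15 higher and 3 lower. In cortex tetraspanins rose in 7 of 12 cases, TET6 by 1.94 ± 0.39, and TET7 fell by 1.93 ± 0.43, and serine carboxypeptidase-like genes had 9 higher, scpl48 at 2.51 ± 0.38, and 3 lower of 22, scpl26 at -1.66 ± 0.25. None of these lists was called by camera in that population.

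Cells may lose part of their own transcript signature within the hour of salt. Genes enriched in each population on the replicate 1 arrays were followed on the other arrays (choice on standard medium), and a median at least 0.3 lower with salt than that of all genes was counted. A loss was to be read from 5 or more of 6 populations, and 2 or fewer were to speak against it. The count was 4 of 6, which decides neither way: epidermis (-1.60, 614 probe sets, 92.8% of them lower), protophloem (-0.80, 830), cortex (-0.65, 419) and stele (-0.56, 234), against 0.16 in columella (756) and 0.06 in endodermis (536). In the other 5 populations the same sets moved by -0.34 to 0.04 (epidermis set), 0.05 to 0.69 (protophloem), -0.10 to 0.15 (cortex) and -0.32 to 0.33 (stele). The endodermis set, at 0.13 to 0.59 elsewhere, was also lowest in its own population, and the columella set, at 0.04 to 0.73 elsewhere, was in columella below its median of 0.41 in the others. A choice on standard medium favours genes that salt lowers. Chosen by the mean of both media, the sets met the same threshold in 2 of 6 populations, epidermis (-0.92, 323 probe sets) and protophloem (-0.77, 656), the latter by -0.10 on replicate 2 and -1.40 on replicate 3. By the bars set for that test, 1 or fewer for an effect of the choice and 4 or more against it, this count is undecided too. The other medians were -0.07 in cortex, 0.04 in stele, -0.02 in endodermis and 0.42 in columella. On replicates 2 and 3 apart, cortex was at 0.32 and -0.48 and endodermis at 0.49 and -0.56, past the threshold on replicate 3. Sets chosen on the salt arrays moved by 0.55 in cortex, 0.58 in stele, 0.70 in columella, 0.15 in epidermis, 0.02 in endodermis and -0.22 in protophloem. Replicates 2 and 3 differed, being at 0.98 and 0.10 for cortex and 0.38 and -0.97 for protophloem in this choice, and at -1.05 and -0.10 for stele and -0.21 and -1.35 for protophloem in that on standard medium.

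As means over the replicates followed, the falls in cortex and stele thus depend on the medium used for the choice, and the replicates of cortex differed in sign in the choice on both media. For epidermis and protophloem, where the GAPDH ratio moved, a loss of identity transcripts, array quality and a changed mix of sorted cells are left open.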
